A study of Homo sapiens with 93 samples.

How the data were processed

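The peak lists come from 4 ChIP-nexus libraries of H9 human embryonic stem cells, 1 each for CTCF and Rad21 in control and heat-shock culture, as the labels name them. The other samples of the series were not analysed here. Each deposited list has 3 columns, chromosome, start and end, with no header, score, height, fold, p-value or strand. The genome build is hg38, per the submitters' processing notes, which also name Bowtie, Juicer, TopHat and Cufflinks without versions or roles. The peak caller, its threshold, the control library and the read depth are not given in the sources used here, and neither is whether the same threshold was applied to both conditions. A difference in depth or threshold between libraries therefore changes the number of peaks and every share computed from them. The labels give 1 list per library, and they name no replicate of these cultures.

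The lists held 130297, 100486, 278016 and 359005 lines for CTCF control, CTCF heat shock, Rad21 control and Rad21 heat shock. Identical lines repeated 4925, 3396, 3407 and 3675 times and were counted once. Peaks on chromosomes 1 to 22, X and Y were kept, and mitochondrial peaks, at most 5 in any list, were left out. After merging of overlapping intervals, each list held a block of peaks of 1 narrowest width, 24, 25, 28 and 31 bp in the same order, which made up 8.21%, 4.22%, 63.5% and 70.5% of peaks. Because of that block, results are also given for the wider peaks, a choice made after the data were examined. Wider means wider than the list's own narrowest width. The cut-off was thus lower for Rad21 control, at 28 bp, than for Rad21 heat shock, at 31 bp, which favours control in counts of wider peaks. The lists held 115076, 92991, 100191 and 104813 wider peaks. Comparisons of equal numbers took the 92991 widest peaks of every list, with ties in width drawn at random.

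Peaks were called shared when they overlapped by at least 1 bp. For the share of peaks found again among wider peaks or equal numbers of peaks, both lists were restricted; for the share of peaks at gene ends and for Rad21 with and without CTCF, absence was judged against the full list of the other condition. For counts of genes, in gene lists and families too, peaks of both conditions were restricted, so that a gene counted as having a wider peak in 1 condition may have a peak of the narrowest width in the other. The chance level of each of the 8 overlap shares came from 1000 placements in which every peak of the first list was moved by 10 to 100 kb to either side, and the one-sided permutation p is the share of placements with an overlap at least as large. The smallest possible value is 0.001, and Benjamini-Hochberg adjustment was made over the 8 shares. Intervals come from 2000 bootstrap draws of 5 Mb blocks. They do not cover variation between cultures or library preparations. With 1 library per protein and condition no test between conditions was possible. Wider Rad21 peaks were called with CTCF when they lay within 100 bp of a CTCF peak of either condition. The overlap and chance calculation was tested on simulated data: lists of 125367 peaks built to share 0, 30 and 60% gave 1.01, 30.5 and 60.2%.

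Genes were taken from a RefSeq table of assembly GRCh38.p14, which has the coordinates of hg38 for the chromosomes used, and which gives gene spans and types without strand or exons. The plan had been to use promoters within 1 kb of a transcription start site. Without strand, a gene was instead called occupied when a peak lay within 1 kb of either end of its span, and random lists were matched on gene length in 10 strata in place of the number of start sites. The CTCF motif was not searched because no genome sequence was used here. Of 211 listed genes, 209 matched a protein-coding symbol and 1 an older symbol; H19 is not protein-coding and was left out. The lists cover heat shock and chaperone genes, pluripotency genes, immediate early genes, cohesin and architectural protein genes, Polycomb and developmental genes, markers of differentiated cells, ubiquitously expressed genes, and clustered protocadherin, beta-globin and imprinted genes.

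The rule for naming genes was fixed before the data were examined, with gene ends later put in place of promoters. Apart from the genes it always names, it picks genes by their values in these data. The rule took, from each list and protein, up to 4 members with a peak in 1 condition only and then members with a peak in both. It also took the 5 strongest peaks at a gene end found in 1 condition only for each protein and condition, the 3 strongest peaks of each list, and CTCF, RAD21, HSPA1A, HSPA1B, DNAJB1, HSPH1, HSP90AA1, POU5F1, NANOG and SOX2. Strength was taken as peak width, the rule's own fallback where files give no score. Members named beyond this rule complete a count or a list and were chosen after their values were seen. Single results of 2 list members are not reported here. Alternatives were an overlap of 50% of the shorter peak, a gap of up to 100 bp, unmerged peaks, all sequence names, rotation of a list along each chromosome, gene-end windows of 500 and 2500 bp, the wider peaks, equal numbers of the widest peaks and, for gene ends, width-matched peaks and equal numbers with absence judged in the restricted lists. Alternatives other than the wider peaks used 100 placements. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used Matplotlib 3.10.9.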

Results

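The series profiled H9 cells, an established human embryonic stem cell line, in normal culture and after heat shock, and it holds 93 samples made with several chromatin and RNA assays. The data analysed here are 4 peak lists from ChIP-nexus, a form of chromatin immunoprecipitation in which an exonuclease trims the bound DNA so that binding sites are mapped more narrowly than by sonication alone. CTCF, a zinc finger protein that binds insulators and the anchors of chromatin loops, and Rad21, a subunit of the cohesin ring, were each profiled in 1 control and 1 heat-shock library. The labels give no temperature or duration for these cultures; for the ATAC-seq cultures of the same series they give 37 °C and 42 °C. After removal of repeated lines and of the mitochondrial chromosome, the CTCF lists held 125367 control and 97086 heat-shock peaks, and the Rad21 lists held 274607 control and 355326 heat-shock peaks. Read depth is unknown because the lists carry positions without counts or scores. No library had a replicate, so no difference between conditions was tested against the spread between cultures. Intervals are 95% intervals from resampling genome blocks of 5 Mb, and they cover variation along the genome within these libraries. Positions are on hg38, and a peak is called control-only or heat-shock-only when no peak of any width in the other condition's list overlaps it by 1 bp or more.

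The first comparison asked how far CTCF occupied the same sites in both conditions. Of the control CTCF peaks, 58.4% (interval 57.7 to 59.1) overlapped a heat-shock peak, and of the heat-shock peaks 75.4% (74.9 to 76.0) overlapped a control peak. The control-only peaks numbered 52180 and the heat-shock-only peaks 23857. With both lists limited to their 92991 widest peaks, these shares were 77.1% and 77.2%, and 21262 control and 21196 heat-shock peaks had no overlap. Among the widest sites were a peak shared by both lists on chromosome 6 at 148366 to 148967, which lay in no annotated gene, and a control peak at 106660069 to 106660621 on chromosome 7 inside CCDC71L. A control peak at 105999408 to 105999982 on chromosome 14 lay in the immunoglobulin heavy chain locus IGH. The heat-shock list was led by a peak of 724 bp at 176596807 to 176597530 on chromosome 5 inside GPRIN1 and a peak of 664 bp at 64285600 to 64286263 on chromosome 20, 9373 bp from PCMTD2. Each of these widest CTCF peaks overlapped a peak in the other condition. The share found again rose with width: 0.496% of control CTCF peaks at the narrowest width of 24 bp overlapped a heat-shock peak, against 97.9% of those of 160 bp or wider. At shared sites CTCF peaks were narrower under heat shock, with a median width of 127 bp against 135 bp in control.

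The widest control-only CTCF peaks at the end of a protein-coding gene lay beside ZNF747 on chromosome 16 at 30535786 to 30536049, at an end of PRR16 on chromosome 5 at 120464124 to 120464364, inside ASAP3 on chromosome 1 at 23484067 to 23484298, 85 bp from SKIL on chromosome 3 at 170357399 to 170357629, and at an end of GPCPD1 on chromosome 20 at 5610795 to 5611021. SKIL encodes a repressor of TGF-beta signalling. Their heat-shock-only counterparts lay at THSD7B on chromosome 2 at 137677621 to 137677868, within 1 kb of COMMD3 and BMI1 on chromosome 10 at 22320530 to 22320763, at ITGB8 on chromosome 7 at 20329710 to 20329937, beside PIGP and TTC3 on chromosome 21 at 37073691 to 37073916, and in CNNM4 on chromosome 2 at 96760947 to 96761169. BMI1 is a component of Polycomb repressive complexes and ITGB8 encodes an integrin subunit. The permutation test, in which each peak of a list was moved by 10 to 100 kb at random, gave a chance overlap of 0.877% for the control list and 1.13% for the heat-shock list, with adjusted p = 0.001 in each direction, the smallest value that 1000 placements allow. That test bears on the overlap of the lists and says nothing about the difference between conditions.

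Rad21 peaks were shared less often over the full lists: 31.5% (31.1 to 32.0) of control peaks overlapped a heat-shock peak and 24.3% (23.9 to 24.8) of heat-shock peaks overlapped a control peak. Both lists were dominated by peaks of a single narrowest width, which was 28 bp for 174416 control peaks and 31 bp for 250513 heat-shock peaks. Among the wider peaks, 72.2% (71.8 to 72.6) of 100191 control peaks and 69.0% (68.6 to 69.3) of 104813 heat-shock peaks overlapped a wider peak of the other condition. Of the widest control Rad21 peaks, the first lay beside TIPARP on chromosome 3 at 156673986 to 156674422, the next on chromosome 12 at 113587676 to 113588103 in no annotated gene, 115804 bp from LHX5, and the third on chromosome 3 at 93470370 to 93470776, 402274 bp from PROS1. The widest heat-shock Rad21 peak measured 553 bp on chromosome 5 at 116864190 to 116864742, in no annotated gene. It was followed by a peak in CRYBG1 on chromosome 6 at 106360356 to 106360770 and by a peak on chromosome 20 at 64285858 to 64286271, overlapping the wide CTCF peak near PCMTD2. At shared sites the median control Rad21 peak was 96.0 bp wide, and heat-shock peaks were wider by a median of 4 bp. Of these sites 58.0% were wider and 41.0% narrower under heat shock. The narrowest width of the lists was itself 28 bp in control and 31 bp under heat shock, so the shift may lie in the lists. Chance overlap was 1.39% for the control and 1.08% for the heat-shock list (permutation test, adjusted p = 0.001 for each, the smallest value possible).

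**Figure D1:**
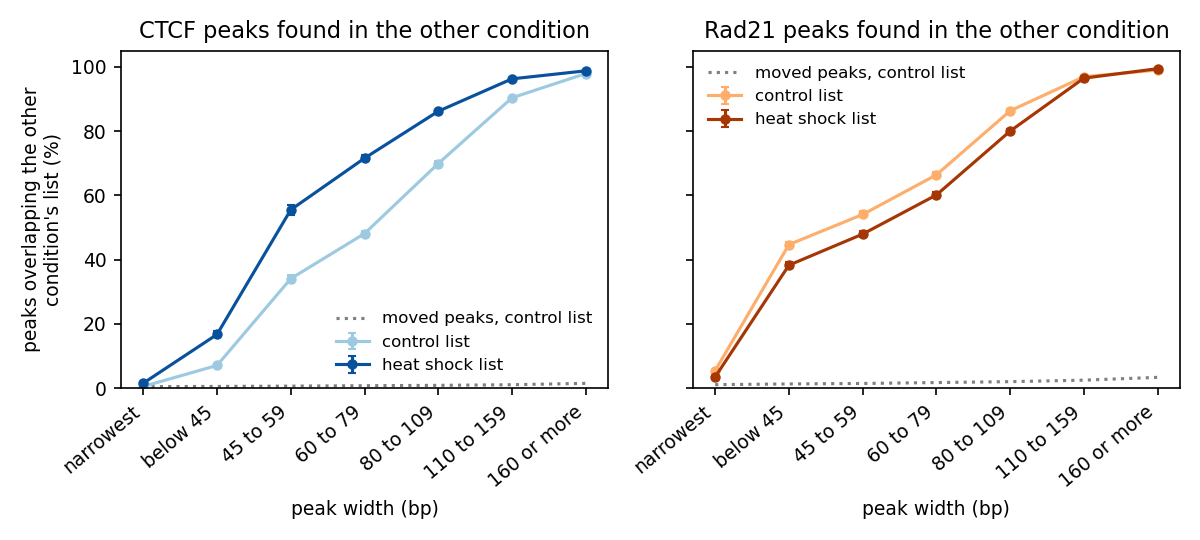
Percentage of CTCF peaks (left) and Rad21 peaks (right) that overlap the other condition's list, by peak width in bp; points are the control and heat-shock lists, error bars 95% genome-block intervals and the dotted line the share after moving the control peaks at random. In control CTCF the share goes from 0.496% at the narrowest width to 97.9% at 160 bp or wider, and in control Rad21 from 5.45% to 99.0%.

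Control-only Rad21 peaks at gene ends were led by a peak 535 bp from ADRB1, the gene of the beta-1 adrenergic receptor, on chromosome 10 at 114043096 to 114043330. The next lay at MRPL3 on chromosome 3 at 131502853 to 131503080, CCDC43 on chromosome 17 at 44689681 to 44689905, RFC1 on chromosome 4 at 39366285 to 39366487, and MRPL2 with KLC4 on chromosome 6 at 43059847 to 43060043. MRPL2 and MRPL3 encode mitochondrial ribosomal proteins, and RFC1 a subunit of the clamp loader of DNA replication. Heat-shock-only Rad21 peaks at gene ends were led by PIGK on chromosome 1 at 77219160 to 77219408, with a width of 249 bp. ZNF33A on chromosome 10 at 38011045 to 38011234, TUT4 on chromosome 1 at 52553037 to 52553219, PTCD2 with MRPS27 on chromosome 5 at 72320534 to 72320712, and ZYG11A on chromosome 1 at 52843103 to 52843280 followed. Each of these 10 peaks overlapped no Rad21 peak of the other condition.

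The next comparison concerned the position of cohesin relative to CTCF. Over the full lists 27.3% (26.8 to 27.8) of control Rad21 peaks and 19.9% (19.4 to 20.3) of heat-shock Rad21 peaks overlapped a CTCF peak of the same condition, and the heat-shock share was lower by a difference of -7.41 percentage points (-7.55 to -7.26). Among peaks wider than the narrowest width the shares were 69.0% in control and 63.1% under heat shock. With equal numbers of widest peaks they were 71.0% and 67.8%, a difference of -3.14 percentage points. In the other direction, 59.03% (58.5 to 59.6) of control CTCF peaks and 72.0% (71.5 to 72.3) of heat-shock CTCF peaks carried Rad21, a difference of 12.9 percentage points. When every list was limited to its 92991 widest peaks, that difference turned to -3.00 percentage points, with 67.7% under heat shock and 70.7% in control. Overlap between the proteins exceeded chance in each of the 4 tests, by 33.52 to 36.04 times, with adjusted p = 0.001, the smallest value possible (permutation test).

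Rad21 sites with CTCF and sites without it differed in how often they were found again. Of the wider control Rad21 peaks, 73638 lay within 100 bp of a CTCF peak of either condition, and 92.1% (91.9 to 92.4) of these overlapped a heat-shock Rad21 peak. The 26553 wider control peaks without CTCF overlapped a heat-shock peak in 34.5% (33.8 to 35.2) of cases. Under heat shock, 90.0% of 76106 wider peaks with CTCF and 31.9% of 28707 without it overlapped a control Rad21 peak. Over Rad21 peaks of any width without CTCF these shares were 7.81% in control and 5.56% under heat shock. Among the wider control Rad21 peaks, those found in both conditions had a median width of 104 bp and control-only ones 53 bp. Sites with and without CTCF were not matched on width, so a difference by CTCF cannot be told apart from one by width. Over all CTCF peaks, control peaks found in both conditions lay within 100 bp of a Rad21 peak in 94.8% of cases, and control-only CTCF peaks in 30.6%, or 56.2% with equal numbers of widest peaks. Peaks found in both conditions were also wider, with a median of 135 bp against 37.0 bp for control-only CTCF peaks.

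Gene ends were then compared, since the annotation used here gives the span of each gene without strand, exons or introns, so that a start site could not be told from a 3' end. Among Rad21 peaks wider than the narrowest width, 17.1% (16.2 to 18.0) of the 23178 control-only peaks lay within 1 kb of an end of a protein-coding gene. The heat-shock-only share was 10.6% (9.97 to 11.3) of 27122 peaks, and that of control peaks found in both conditions was 8.85% (8.34 to 9.37). Moving the control-only peaks at random gave 3.44%. Over all Rad21 peaks the control-only share was 6.51% and the heat-shock-only share 4.60%, a difference of 1.92 percentage points (1.76 to 2.08). By number, 12244 control-only and 12357 heat-shock-only Rad21 peaks lay at gene ends over all peaks, and 3963 and 2878 among the wider peaks. By share CTCF showed the opposite order, with 4.98% (4.60 to 5.38) of wider control-only peaks and 8.19% (7.62 to 8.77) of wider heat-shock-only peaks at gene ends. Over all CTCF peaks these shares were 4.39% and 7.20%, a difference of -2.81 percentage points (-3.22 to -2.40). By number, 2289 control-only and 1717 heat-shock-only CTCF peaks lay at gene ends over all peaks, and 2089 and 1624 among the wider peaks. Among the 92991 widest peaks of each list these counts were 1424 and 1624. They were 1426 and 1720 when absence was judged in those restricted lists too.

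**Figure D2:**
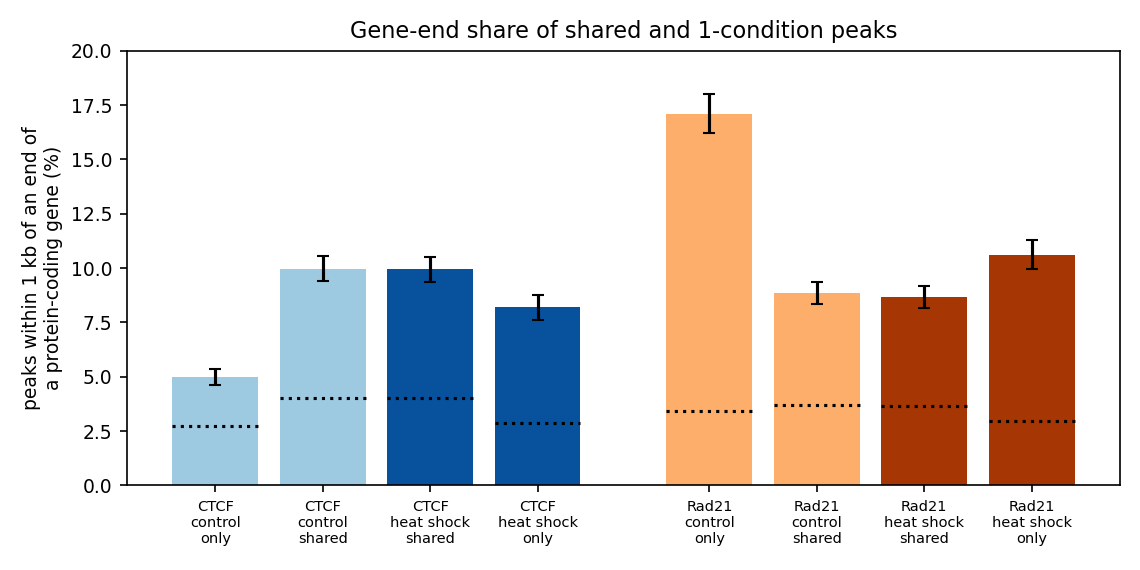
Percentage of peaks wider than the narrowest width that lie within 1 kb of an end of a protein-coding gene, for peaks found in 1 condition only or shared, by protein and list; error bars are 95% genome-block intervals and dotted lines the share after moving the peaks at random. The control-only Rad21 bar stands at 17.1% against 10.6% for heat-shock-only Rad21, and the CTCF bars, also shares of each class, are in the opposite order at 4.98% and 8.19%.

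Of the 20037 protein-coding genes, 12867 had a Rad21 peak at an end in control and 13027 under heat shock, with 10546 in both, 2321 in control only and 2481 under heat shock only. When the wider peaks of both lists were counted, these counts were 9123 in control and 8415 under heat shock, and the order of the remainder turned, with 2318 genes having a wider peak in control only and 1610 under heat shock only. Within 2500 bp of an end, over all peaks, 1335 genes had Rad21 in control only and 1940 under heat shock only. CTCF peaks lay at the ends of 8397 genes in control and 8032 under heat shock, with 1438 in control only and 1073 under heat shock only. That order turned when every list was limited to its 92991 widest peaks, where 923 genes had CTCF in control only and 1143 under heat shock only. RAD21 itself had a control-only Rad21 peak of 28 bp on chromosome 8 at 116874406 to 116874433, and CTCF had Rad21 in both conditions on chromosome 16, 172 bp wide at 67562713 to 67562884 in control.

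Gene lists fixed before the data were examined were set against 10000 random lists matched on gene length. Of the 38 heat shock and chaperone genes, 29 had a Rad21 peak at an end in control and 30 under heat shock, above the median of 23 and 24 in random lists (percentiles 97.2 and 98.2). With the wider peaks 21 and 17 members had one (percentiles 93.0 and 72.4). Rad21 was listed in control only at HSPA9, HSPD1, HSPE1 and SERPINH1, and under heat shock only at AHSA1, BAG3, FKBP4, HSF1 and HSPB8, where random lists gave medians of 4 and 5. Except at SERPINH1 and HSPB8, these peaks were of the narrowest width, HSF1 and BAG3 included. HSF1 encodes the main transcription factor of the heat shock response and BAG3 a co-chaperone of HSP70. A wider Rad21 peak was present in control and not under heat shock at 6 members (DNAJA1, HSF2, HSP90AA1, HSPA4, HSPA8 and SERPINH1) and under heat shock and not in control at 2 (HSP90B1 and HSPB8), at percentiles 83.5 and 31.9; all of these except SERPINH1 and HSPB8 had a Rad21 peak of the narrowest width in the other condition. CTCF lay at 19 members in control and 14 under heat shock. Its 5 control-only members were HSPA1B, HSPA5, HSPD1, MRPL18 and TCP1, at percentile 92.4, and it had no heat-shock-only member, at percentile 7.29. With equal numbers of widest peaks CTCF was control-only at 2 members, at percentile 64.0. MRPL18 and TCP1 share the peak on chromosome 6 at 159790433 to 159790474.

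Single chaperone genes differed in where the peaks lay. At HSP90AA1 on chromosome 14 the widest control Rad21 peak measured 94 bp at 102139384 to 102139477, inside the CTCF peak of 110 bp, while the widest heat-shock Rad21 peak at a gene end measured 31 bp and lay 1236 bp away. HSPH1 on chromosome 13 had CTCF in both conditions, 66 bp wide in control and 82 bp under heat shock, and its Rad21 peaks were of the narrowest width. HSPA1A and HSPA1B, the inducible HSP70 genes, had control Rad21 peaks of 53 bp at 31815597 to 31815649 and of 47 bp at 31827754 to 31827800 on chromosome 6. Under heat shock no Rad21 peak overlapped either position. The heat-shock list instead held a peak of 65 bp at 31814619 to 31814683 and a peak of 129 bp at 31830017 to 31830145, the latter over the control-only CTCF peak of HSPA1B. The 2 genes are near-identical copies, so reads could be assigned to either and these positions are uncertain. DNAJB1 had neither protein within 1 kb of an end of its span, 14514769 to 14560391 on chromosome 19, in either condition. Inside that span or within 10 kb of it lay 5 wider Rad21 peaks in each condition. Wider CTCF peaks there numbered 6 in control and 7 under heat shock. A start site inside the span would not have been examined.

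**Figure D3:**
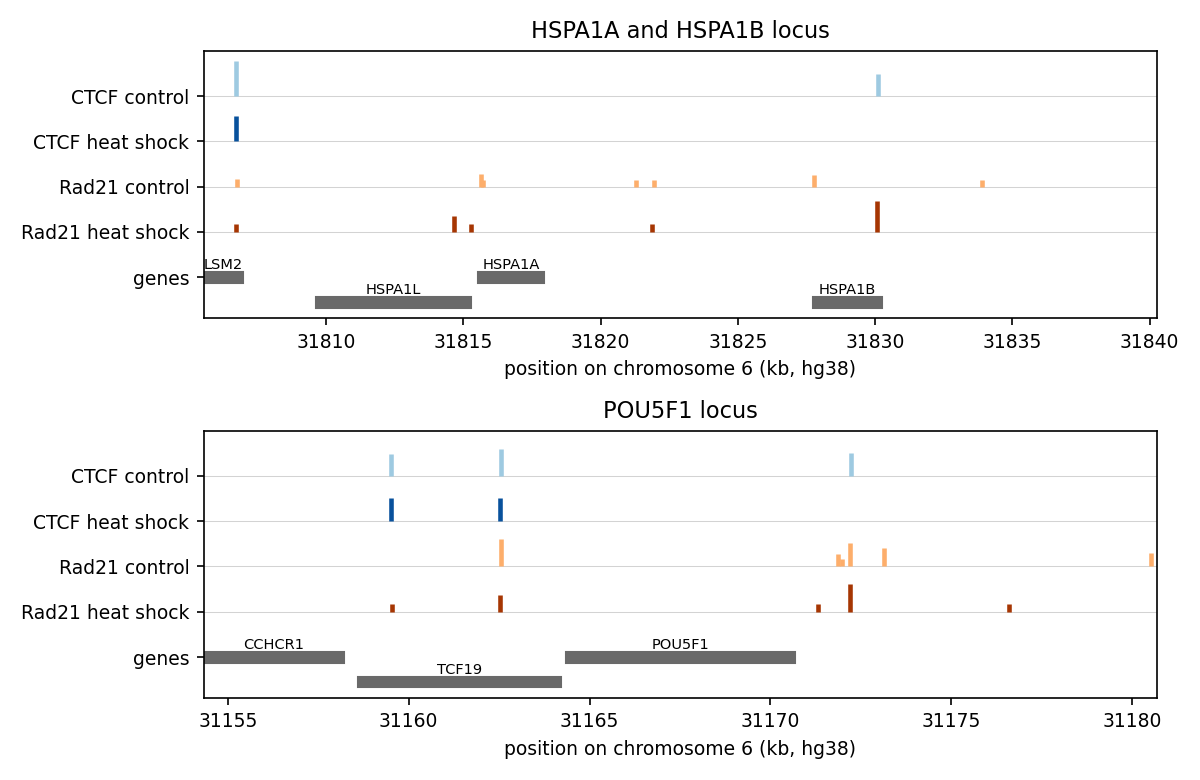
Peaks of the 4 libraries around HSPA1A and HSPA1B (top) and POU5F1 (bottom) on chromosome 6, with position in kb on the x axis and gene spans as grey bars; each vertical line marks 1 peak, its height is proportional to the peak's width up to 144 bp and its thickness is not to scale. At HSPA1B the 129 bp heat-shock Rad21 peak lies over the 92 bp control CTCF peak, and above POU5F1 the Rad21 peak at 31172151 to 31172249 is present in both conditions.

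Of the 33 pluripotency genes, 19 had Rad21 at an end in control and 20 under heat shock, and 13 in both. The 6 control-only members included DPPA2, LEFTY2, NANOG, TERF1 and ZFP42, and the 7 heat-shock-only members were FGF2, JARID2, NODAL, OTX2, POU5F1, SALL4 and TFCP2L1, at percentiles 87.6 and 92.8 of random lists. Counting wider peaks of both lists, 7 members had one in control only and 7 under heat shock only, at percentiles 96.3 and 99.2, and DPPA2, FGF2, JARID2, NODAL, OTX2 and SALL4 were in the same class as over all peaks. Within 2500 bp of a gene end the counts were 3 control-only and 0 heat-shock-only. The DPPA2 peak measured 121 bp on chromosome 3 at 109316498 to 109316618, across the end of the gene. FGF2, which encodes a growth factor that sustains human embryonic stem cells, had a heat-shock peak of 84 bp on chromosome 4 at 122826504 to 122826587, and SALL4, a stem cell transcription factor, one of 59 bp on chromosome 20 at 51801554 to 51801612. At POU5F1, which encodes OCT4, the heat-shock-only peak was 31 bp wide at 31171311 to 31171341 on chromosome 6, and at NANOG the control-only peak was 28 bp wide at 7798227 to 7798254 on chromosome 12. CTCF lay at 9 members in each condition, against a median of 13 in random lists (percentiles 5.36 and 8.33), and at 20 and 21 within 2500 bp (percentiles 54.0 and 79.7). Its 3 control-only members included ESRRB and NODAL, and it was heat-shock-only at CD24, OTX2 and SALL4. SOX2 had neither protein at an end.

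The Polycomb and developmental list had Rad21 at 17 of 32 members in each condition, with 10 in both. The 7 control-only Rad21 members included DLX5, GATA3, NKX2-1, NKX2-5, PAX3 and ZIC1, and the 7 heat-shock-only members were HOXA2, HOXB4, HOXC4, HOXD1, PAX6, PAX7 and TBX5, at percentiles 95.3 and 93.6. At DLX5, PAX3, ZIC1, HOXA2, HOXB4, HOXC4, PAX6 and TBX5 these Rad21 peaks were of the narrowest width. Counting wider peaks of both lists, 5 members had one in control only and 3 under heat shock only, at percentiles 82.7 and 70.6. Within 2500 bp these counts were 4 and 2 (percentiles 87.4 and 23.7), and among the widest peaks in equal numbers 3 and 4 (percentiles 44.8 and 89.4). CTCF lay at 15 members in control and 18 under heat shock, the latter at percentile 98.0. Its 4 heat-shock-only members included HOXD1, PAX2 and TBX5, with peaks of 95, 93 and 88 bp, and GATA3 was the control-only member. With the wider peaks, and with equal numbers, 5 members had CTCF under heat shock only (percentiles 98.7 and 98.1), and within 2500 bp 1 did, where CTCF lay at 27 members in control and 26 under heat shock (percentiles 99.97 and 99.92).

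Immediate early genes, which are induced within minutes of many stimuli, had Rad21 at 14 of 25 members in control and 18 under heat shock. The heat-shock-only members ATF3, EGR1, EGR3, GADD45B and KLF10 (percentile 86.8) each had a peak of the narrowest width, and IER5 was control-only (percentile 13.3). Counting wider peaks of both lists, 1 member had one in control only and 1 under heat shock only. CTCF lay at 14 members in each condition. It was heat-shock-only at FOS, with a peak of 148 bp on chromosome 14 at 75278808 to 75278955, and at EGR1, and control-only at EGR3 and GADD45A.

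Of the 22 cohesin and architectural protein genes, 17 had Rad21 in control and 16 under heat shock. Control-only members were RAD21, SMARCA4 and WAPL, the last encoding the cohesin release factor, and heat-shock-only members were RNF2 and SMC1A, at percentiles 61.8 and 33.2. CTCF was control-only at MAU2 and NCAPH2 and heat-shock-only at ZNF143. The clustered protocadherin, beta-globin and imprinted genes, chosen as known CTCF targets, had CTCF at 13 of 17 members in control and 14 under heat shock, against a median of 7 in random lists (percentiles 99.63 and 99.98). Protocadherin members that share an end also share its peak, so they are not independent as the genes of random lists mostly are. PCDHAC2 differed between conditions, with a control-only Rad21 peak of 114 bp at 140967034 to 140967147 and a heat-shock-only CTCF peak of 89 bp at 140966050 to 140966138 on chromosome 5. HBB, HBE1 and KCNQ1 had heat-shock-only Rad21 peaks of 31 bp. PCDHGA1, PCDHGB1 and PCDHGC3 share a CTCF peak at their common end, 295 bp wide in control and 333 bp under heat shock.

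Markers of differentiated cells had Rad21 at 17 of 25 members in control and 18 under heat shock, control-only at KRT8 and NEUROD1 and heat-shock-only at FOXA2, HAND1 and MIXL1, at percentiles 31.1 and 50.7. CTCF lay at 15 and 14 members, with SOX1 control-only. Of 18 ubiquitously expressed genes, 17 had Rad21 in control and 16 under heat shock, above the median of 12 in random lists (percentiles 99.8 and 98.7), and UBE2D2 was control-only. With the wider peaks 10 and 11 members had Rad21 (percentiles 80.1 and 95.2). CTCF lay at 11 members in control and 13 under heat shock, heat-shock-only at RPL13A and TFRC. RPLP0 and SDHA had CTCF at overlapping positions in both conditions, as did COL1A1 and GATA4 among the markers, whereas the widest CTCF peaks at EOMES lay 404 bp apart. GAPDH had Rad21 at overlapping positions in both conditions, 107 bp wide in control and 99 bp under heat shock, while the widest Rad21 peaks of the 2 conditions lay 1359 bp apart at POLR2A and 1189 bp apart at TUBA1B. No percentile was corrected for the 8 lists and 2 proteins, and percentiles describe these libraries without replicates.

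**Figure D4:**
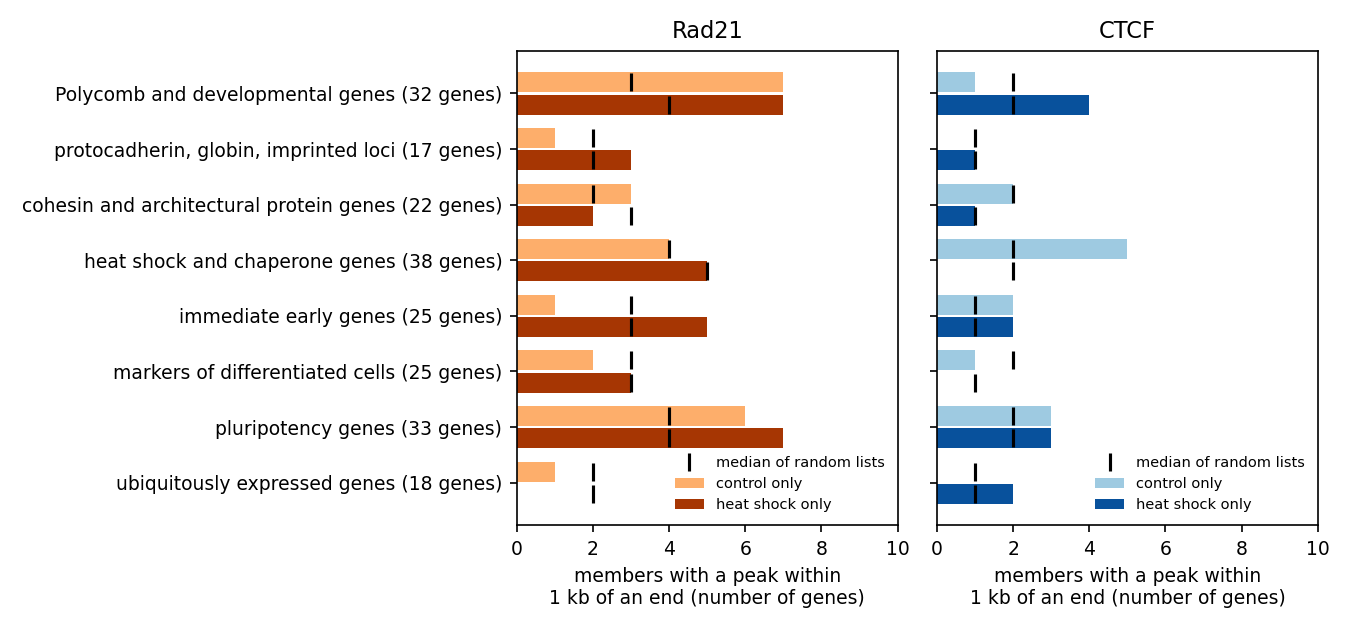
Number of members of each fixed gene list (x axis, genes) with a Rad21 peak (left) or CTCF peak (right) within 1 kb of a gene end in control only or under heat shock only, over all peaks; black ticks mark the median of 10000 random lists matched on gene length. Rad21 is control-only at 6 and heat-shock-only at 7 of the 33 pluripotency genes, and CTCF is control-only at 5 and heat-shock-only at 0 of the 38 heat shock and chaperone genes.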

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

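The gene-end shares over all peaks were planned; the values for wider peaks and equal lists, and every test of an explanation in this part, were chosen, or changed in how they were computed, after results had been seen. The shares of Rad21 and CTCF peaks at gene ends differed in opposite directions between the same pair of conditions. Control-only minus heat-shock-only, the share at gene ends was 1.92 percentage points for Rad21 and -2.81 for CTCF over all peaks, and 6.49 and -3.21 over the wider peaks. The difference between the proteins was not tested, since each direction rests on 1 library per condition. By number the direction for CTCF depended on list length: 2089 control-only and 1624 heat-shock-only wider peaks lay at gene ends, and 1426 and 1720 in lists of 92991 peaks each, with absence judged in those lists. An earlier explanation, a loss of gene-end signal in every heat-shock library, was set aside on the CTCF share of -3.21 and replaced by dilution. In lists of 92991 peaks each, with classes of similar length, the CTCF difference was -1.41 points (-1.87 to -0.923). The CTCF lists of that length reached down to 42 bp in control and 26 bp under heat shock. Detection was thus not equalised, the value does not decide on that loss, and the loss stays open.

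For Rad21, a difference of 5.16 points (4.54 to 5.78) remained in lists of 92991 peaks each, with absence judged in those lists. These lists reached down to 36 bp in control and 44 bp under heat shock. Equal length therefore does not equalise detection, and lower sensitivity of the heat-shock library stays open. Unequal widths as the whole cause are argued against by a difference of 6.59 (5.93 to 7.25) averaged within width classes. Dilution by extra background peaks would not lower the number of peaks at gene ends. Among the wider peaks 1.38 (1.32 to 1.45) control-only peaks lay there for each heat-shock-only peak. That count favours control, since its cut-off was 28 bp in control and 31 bp under heat shock, so it does not decide on dilution. Over all peaks that ratio was 0.991 (0.966 to 1.02), and dilution stays open there too. A difference in background at open chromatin between the Rad21 preparations also stays open, as it cannot be separated from heat shock with 1 library each, and a loss of cohesin from gene ends under heat shock is a hypothesis untested here.

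The heat-shock Rad21 list was longer by 80719 peaks, and 94.3% of that excess was at the narrowest width. This is consistent with a difference in how many weak sites passed the caller's threshold, from depth or from the threshold itself, neither of which is known. No biological explanation was tested for it.

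The heat-shock CTCF list was shorter, with 28323 more control-only than heat-shock-only peaks, and weaker detection of narrow peaks was weighed as an explanation. Peaks of 160 bp or wider made up 0.967% of that excess. This measure was chosen last, with its value known when its bounds were set, after a ratio of shares found again (13.9, widest to narrow control peaks) was dropped as true of all 4 lists and the part of the excess below 80 bp (81.3%) as too near its bound. With nearly all of the widest peaks found again it could hardly have come out otherwise, so it decides nothing, and weaker detection and less binding of CTCF under heat shock both stay open.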

How the results depend on the processing

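The wider peaks, equal numbers of widest peaks and width matching, and every value of the CTCF at Rad21 and gene ratio results, were chosen after seeing the data; the other alternatives were planned. All 56 alternative values of the 8 overlap shares stayed above chance with p below 0.05 in the permutation test. Control Rad21 peaks found under heat shock ranged from 29.5% to 72.2% and Rad21 at CTCF in control from 26.4% to 71.0%, the upper values coming from lists without the narrowest peaks or of equal length, by construction. Rad21 at CTCF, heat shock minus control, was -7.13 points with 50% overlap, -7.96 with a 100 bp gap, -5.87 with the wider peaks and -3.14 with equal numbers. CTCF at Rad21, heat shock minus control, was 12.3 with unmerged peaks and 11.1 with the wider peaks, and turned to -3.00 with equal numbers. There the CTCF control list and both Rad21 lists were shortened at once, so the turn cannot be put down to any one of them. Control-only minus heat-shock-only gene-end shares were 1.56 for Rad21 and -2.08 for CTCF within 500 bp, 6.48 and -1.48 with equal numbers, 5.16 and -1.41 with absence judged in those equal lists too, and 6.59 and -3.35 with matched widths; with the wider peaks Rad21 gave 6.49. Genes with Rad21 at an end in control only, per gene under heat shock only, went from 0.936 to 1.44 with the wider peaks and 1.59 with equal numbers, and to 0.688 within 2500 bp. For CTCF this ratio went from 1.34 to 0.808 with equal numbers and 1.64 within 2500 bp. Over the 8 lists, Rad21 was control-only at 15 members and heat-shock-only at 11 within 2500 bp, against 25 and 32 within 1 kb, and the order turned to 29 and 21 with the wider peaks and 25 and 22 with equal numbers; CTCF was control-only at 8 with equal numbers, against 14. The cause of these changes was not tested where none is named. The alternatives by peak score, for which equal numbers by width stand in, and the motif search were not run. Depth is unknown and limits every count of peaks in 1 condition only. No paired analysis was possible because each ChIP-nexus group has 1 library.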

Other observations

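All tests in this part were chosen after the results that prompted them were seen. The counting of peaks around gene spans, the gene families and the gene types were not planned. Gene types differed in how often a wider Rad21 peak lay within 1 kb of an end. For protein-coding genes the share was 45.5% in control and 42.0% under heat shock, a difference of -3.53 percentage points (-4.21 to -2.84). Over all peaks it was 64.2% and 65.0%, a difference of 0.799 points (0.103 to 1.54) in the other direction. With the wider peaks the share after moving the genes at random was 17.5% and 17.9%. Over all peaks it was 33.65% and 39.68%, a larger rise than the observed one, so the turn there does not show more Rad21 under heat shock. Of 443 tRNA genes, 32.3% had a wider Rad21 peak in control and 28.0% under heat shock, a difference of -4.29 points (-12.4 to -0.114), against 11.1% and 11.2% after moving. Pseudogenes went the other way by 0.668 points (0.353 to 0.999), from 8.88% to 9.55%, close to the 8.998% and 9.51% after moving, and over all peaks they went from 21.4% to 26.9%, against 20.99% and 26.5% after moving. With the wider peaks the intervals of the differences for snRNA, snoRNA and miRNA genes held 0, and lncRNA genes differed by -0.656 points (-1.16 to -0.178). Over all peaks the direction for lncRNA genes turned, with a difference of 4.88 points (4.06 to 5.67), and the differences were 4.55 points for snRNA (0.0 to 9.78), 3.34 for snoRNA (0.239 to 6.27) and 3.35 for miRNA genes (1.04 to 5.74). The shares after moving also rose over all peaks, from 32.27% to 39.26% for lncRNA and from 17.27% to 19.48% for snRNA genes. They rose from 19.07% to 24.17% for snoRNA and from 20.46% to 24.38% for miRNA genes. Of 53 clustered protocadherin genes, 52 had CTCF in each condition, and 50 had a wider Rad21 peak in control and 47 under heat shock, so that 3 of the 50 lost it where random sets of genes with a control peak lost 14.0 to 38.0%. Many of these genes share an end and so the same peak, so they are not independent as the genes of random sets mostly are. Of 36 olfactory receptor genes with a wider CTCF peak in control, 44.4% had no wider CTCF peak under heat shock, above the 5.56 to 27.8% of random sets; 11 others had one under heat shock only, so that the total went from 36 to 31.

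Rad21 peaks without CTCF were counted within 10 kb of each gene's span, using the wider peaks. Totals are sums over genes, so a peak near several genes counts once for each, as at HSPA1A, HSPA1B and HSPA1L. Random lists were matched on gene length and not on such neighbours. Over the 33 pluripotency genes the sum was 57 in control and 38 under heat shock, with fewer under heat shock at 17 members and more at 8. POU5F1 had 4 in control and 0 under heat shock, PODXL 3 and 0, and GDF3, TERF1 and ZSCAN10 2 and 0 each, while JARID2 had 3 and 5. The 4 at POU5F1 included a control peak of 29 bp, below the heat-shock cut-off, and heat-shock peaks of 31 bp there were not counted. The heat shock and chaperone genes had 20 in control and 27 under heat shock, with DNAJB6 and HSPB8 at 0 and 2, at percentile 6.79 of random lists. The other 6 lists lay between percentiles 16.7 and 79.9.

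Against 10000 random lists of genes of like length, the excess of 19 in the summed counts lay at percentile 99.8, where random lists ran from -12.0 to 13.0. With equal numbers of widest peaks it lay at percentile 99.2. Leaving out each member in turn gave percentiles from 98.9, without POU5F1, to 99.9. With all peaks, the narrowest included, the counts were 183 in control and 202 under heat shock, and percentile 92.0 no longer lay outside the central range. The percentile is the value that drew attention to this list, the most extreme of 8, so it restates the observation and does not test it, and no replicate bears on it.

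Ribosomal protein genes had a wider Rad21 peak at 52 of 91 members in control and 39 under heat shock, and 36.5% of the 52 had no wider peak under heat shock. The hypothesis of a higher loss than at other genes with a wider control peak was not borne out: the share lay at percentile 96.7, at the upper edge of the central range of 13.5 to 36.5%. Proteasome subunit genes (13 of 31 genes with a wider control peak had no wider heat-shock peak, percentile 97.7) and complex I subunit genes (12 of 28, percentile 97.7) also lay at the upper edge of their ranges, and each had 5 genes with a wider peak under heat shock only. Over all peaks 74 ribosomal protein genes had Rad21 in control and 59 under heat shock, while the number over all protein-coding genes went from 12867 to 13027. For proteasome genes the all-peak counts were 39 and 36, and for complex I the order turned, with 35 and 37. No percentile was computed for the all-peak counts. Mitochondrial ribosomal protein genes lay at percentile 41.3, with 11 genes in control only and 10 under heat shock only. The number of genes with a wider Rad21 peak was 11 in control and 14 under heat shock for the 40 HOX genes. It was 24 and 30 for the 392 olfactory receptor genes, and 20 and 26 for the 152 genes counted as keratin genes. There was no correction for the 9 families and 2 proteins examined.

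Long genes showed the reverse. Summed over the 315 genes longer than 500 kb, the counts of wider Rad21 peaks without CTCF were 2246 in control and 2567 under heat shock. Over the 9023 genes shorter than 20 kb the sums were 3783 and 3377. The log2 ratio of heat shock to control was higher by 0.22 (0.13 to 0.31) in genes longer than 500 kb than in the rest. That direction was set after the results that prompted it were seen, so the interval restates the observation and does not test it. The genes with the largest gains included CELF2 (7 and 21 peaks), OPCML (9 and 22) and LRMDA (11 and 24), and those with the largest losses RAD51B (32 and 17), SDK2 (9 and 0) and SOX5 (21 and 12). RAD51B and SOX5 are themselves longer than 500 kb, so the direction did not hold at every long gene. No explanation was tested for this difference.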
